A study of Arabidopsis thaliana with 24 samples.

How the data were processed

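The series profiled whole-genome expression in Arabidopsis thaliana on 24 single-channel Affymetrix ATH1 arrays. Plants of the wild type and of the tbf1 mutant were grown for 3 weeks at 22 °C under 16 h of light and 8 h of dark. They were sprayed with 1 mM salicylic acid (SA) or with water and sampled after 6 h, or infiltrated with 10 µM elf18 or with water and sampled after 2 h. The 8 groups had 3 arrays each, which the labels call biological replicates. Nothing further says how separate the plants of the replicates were, so p-values measure the spread between these arrays.

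The deposited values were read as log2 expression values made with RMA (robust multi-array average), per the submitters' processing notes; the version is not given in the sources used here. The log base is not stated in the labels and was taken as 2 because RMA works on that scale, so every fold rests on that reading. In the deposited table each of the 22810 probe sets had been centred on its own median over the 24 arrays. The largest absolute probe set median was 5e-07 and the largest absolute value was 5.30. Brightness above background was lost with this centring, while differences between arrays were kept, and the values run in the direction of expression. The column medians for replicates 1, 2 and 3 were -0.02, -0.03 and 0.00 in wild type water spray, -0.02, -0.02 and -0.01 in wild type SA spray, -0.02, -0.02 and -0.05 in wild type water infiltration, and 0.02, 0.04 and 0.05 in wild type elf18 infiltration. They were 0.08, 0.12 and 0.10 in tbf1 water spray, 0.07, 0.05 and 0.05 in tbf1 SA spray, -0.05, -0.03 and -0.04 in tbf1 water infiltration, and -0.01, 0.01 and 0.00 in tbf1 elf18 infiltration. The array-wide centre was left as deposited, and scans, slides and dates were not used here.

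The 64 control probe sets were left out of the tests, which ran on 22746 probe sets. In the annotation used here 13513 probe sets had 1 gene name, 503 had several and 8730 had none. An unlisted probe set is unnamed here, which does not mean that it has no gene. Of the probe sets with 1 gene, 13436 were matched by Entrez identifier to the RefSeq gene table of assembly TAIR10.1 for current symbols, and 77 kept the name in the annotation. No coordinates are given because the files name no genome build. No probe set was named for TBF1 (AT4G36990, listed in RefSeq as HSF4), so the transcript of the mutated gene, which would have checked the mutant labels, is not analysed here.

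All 24 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group and 16 residual degrees of freedom. The fit uses 1 spread per probe set for all groups, but the spread differed between groups. The mean SD over probe sets was 0.24 in tbf1 water spray, 0.205 in wild type elf18 infiltration and 0.16 in tbf1 SA spray. In the other groups it was 0.11 to 0.13. P-values of comparisons with the wider groups may therefore be too small, and those of the others too large. Contrasts were tested with lmFit, contrasts.fit and eBayes, and p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets of each contrast. A probe set was called at an adjusted p below 0.05. The difference between genotypes in a response was tested as the interaction, tbf1 minus wild type. The comparisons, their tests, 25 gene lists and the naming rule were chosen before the data were examined.

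For each contrast the rule took, from called probe sets with 1 gene name and with no overlap between the values of the groups, the 8 largest rises and the 8 largest falls; the interactions had no overlap condition. For each list and contrast it took up to 4 called members and up to 2 members that were not called, each by size of change. TBF1 was also to be named in each contrast. A brightest probe set per gene could not be chosen on centred values. For lists, plain probe sets were therefore preferred over those of shared classes (names ending in s_at or x_at), and the remaining ones were averaged per gene, giving 13350 genes.

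Of 462 entries in the 25 lists fixed beforehand, 60 had a probe set of their own. The 3 lists with at least 5 such members were tested, namely ER folding and secretion, pattern-triggered immunity, and photosynthesis and chlorophyll. The other 22 lists were too small for a test. Because so few members were named, 17 further lists were added after the data had been opened, from gene names in the annotation alone and before the values of any gene had been tested. Lists were tested with camera at a preset correlation of 0.01, adjusted within the 3 lists and within the 17 lists of each contrast. The alternatives were an estimated correlation and fry. Entries measured only by a probe set with several gene names were left out, although the plan had allowed them.

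An index of RNA quality was taken from 6 pairs of control probe sets for actin, GAPDH and ubiquitin, as the mean difference between the 5' and the 3' probe set. Because the values are centred, the index compares arrays and is not a ratio of intensities. The fit was tested on simulated data with the real group sizes and 66 or 67 changed probe sets per size of change. Noise was independent between probe sets, with 1 spread per probe set, estimated from the real arrays, for all groups. For SA in wild type, 41.8% of true changes of 0.5 on the log2 scale were recovered over 22746 probe sets, 94% of changes of 1, and 100% of changes of 2. For the interaction with SA the same shares were 11.9%, 67.2% and 98.5%. In each simulation, 9 of 22546 unchanged probe sets were called. This does not give the error rate of the real fits, where spreads differed between groups and many more probe sets were called. The number of arrays limits the precision of every comparison.

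The alternatives tried were the replicate number as a block, only the arrays of the groups compared, and arrays centred on their median. Others were quantile normalization, a fold minimum, a stricter threshold, and each array left out in turn. Quantile normalization was run on the centred values, so it made the spread of deviations equal between arrays and rescaled changes. It did not repeat a normalization of intensities. Before it, the SD of an array ran from 0.40 in wild type water infiltration to 0.77 in tbf1 water spray. A call lost or turned with it shows a dependence on that rescaling. A robust eBayes fit, the RNA quality index as a covariate and the mean of the probe sets of a gene, in place of the planned brightest probe set, were added after the data were seen.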

Results

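Transcript levels were measured in wild type and tbf1 plants after SA, a defence hormone, and after elf18, a peptide of bacterial elongation factor Tu that the receptor EFR perceives. TBF1 is a heat shock factor-like transcription factor, and the design asks how far both responses differ when it is mutated. Each of the 8 groups had 3 arrays. Replicates of a group correlated with each other at 0.84 to 0.96 across probe sets, and arrays of different groups at no more than 0.68. The first and second principal components held 37.7% and 34.0% of the variance. On the first, tbf1 arrays lay at both ends, from -91.48 to -65.39 after spraying and from 69.26 to 78.9 after water infiltration. These groups also had the lowest and highest means of the 5' minus 3' index given below. Wild type water spray, whose index was close to the highest, lay between -4.6 and 7.34, so the component followed the index only in part.

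Control probe sets for actin, GAPDH and ubiquitin differed between the groups. The 5' minus 3' index was 0.78 ± 0.08 (SD, n = 3, log2) in wild type after water spray and 0.48 ± 0.20 after SA. It was 0.31 ± 0.00 in wild type after water infiltration and -0.98 ± 0.16 after elf18. In tbf1 it was -1.67 ± 0.29 after water spray, -1.53 ± 0.05 after SA, 0.84 ± 0.07 after water infiltration and -0.34 ± 0.06 after elf18. Ranges did not overlap between tbf1 and wild type under any of the 4 treatments, and the smallest p that an exact two-sided permutation test of 3 against 3 arrays can give is 0.1.

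**Figure D1:**
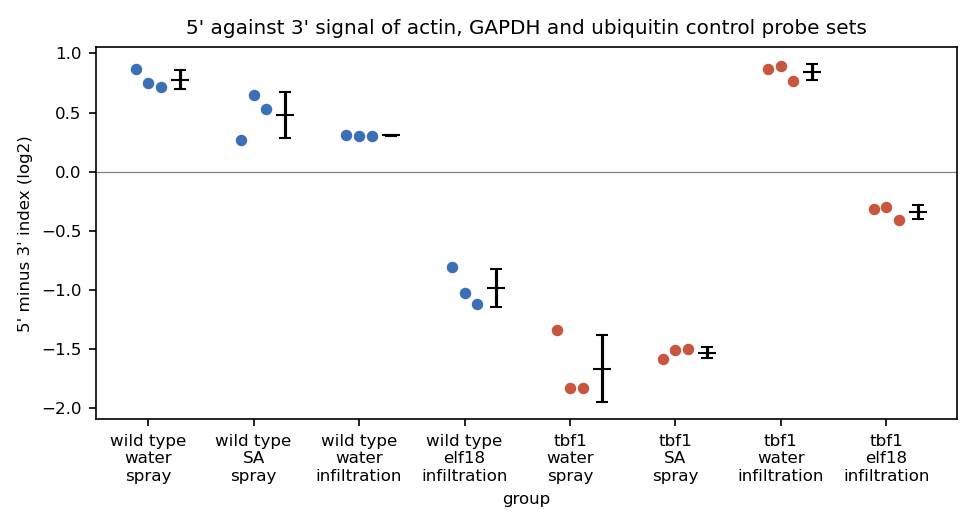
5' minus 3' index (log2) of each array by group, with points for the arrays and bars for mean ± SD (n = 3). The tbf1 spray groups lie lowest, with means of -1.67 and -1.53.

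In wild type plants SA raised UGT76B1 (AT3G11340), a glucosyltransferase of SA and isoleucic acid, by 6.24 ± 0.35 on the log2 scale (SE, 3 arrays against 3, 75.8-fold, adjusted p = 4.87e-13, limma). GRX480 (AT1G28480), a glutaredoxin that binds TGA transcription factors, rose by 3.86 ± 0.10, the ATPase gene AT3G28510 by 3.70 ± 0.15 and AT1G13470 by 3.61 ± 0.15. Rises of 3.31 to 3.57 were measured for AT1G08050, AT4G22530, AT3G13610, an enzyme of scopoletin synthesis, and AT4G01700, a chitinase family member. The largest fall was that of AT5G48490, a lipid transfer protein, at -4.43 ± 0.10. STOMAGEN (AT4G12970), a secreted peptide that promotes stomatal development, was at -3.34 ± 0.15 and GH9C2 (AT1G64390), an endoglucanase, at -3.07 ± 0.23. AT1G12845, AT5G01015, AT2G43550, AT1G13650 and AT5G62360 lay between -3.92 and -3.21.

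All 8 measured genes of ER folding and secretion rose after SA in wild type, also when adjusted over the list alone, with a median of 1.51 (camera adjusted p = 1.82e-10). ATERDJ3B (AT3G62600), a co-chaperone of the ER, rose by 2.44 ± 0.21, AT5G07340, a calnexin, by 1.89 ± 0.18, CRT1b (AT1G09210), a calreticulin, by 1.78 ± 0.19, and the translocon gene AT1G29310 by 1.72 ± 0.13. In the wider list of ER folding, translocation and quality control, 27 of 34 genes rose and none fell, with a median of 0.81 (adjusted p = 3.75e-16). Of 7 pattern-triggered immunity genes 4 rose and none fell, also when adjusted over the list alone, with a median of 0.72 (adjusted p = 0.000168). These were WRKY53 at 3.03 ± 0.13, PUB24 at 2.27 ± 0.12, the kinase gene BIK1 at 0.87 ± 0.12 and the elf18 receptor gene EFR at 0.72 ± 0.17, while PUB23 was at 0.22 and WRKY22 at -0.10.

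With SA, 4 of 9 photosynthesis and chlorophyll genes fell in wild type, and 6 when adjusted over the list alone, with a median of -0.20 (adjusted p = 0.0147). This call was lost with an estimated correlation (adjusted p = 0.0839 with an estimated correlation). PORB, a protochlorophyllide oxidoreductase, was at -0.75, PRK, phosphoribulokinase of the Calvin cycle, at -0.45, and SBPASE and PSAN at -0.29 each. In the wider list of nuclear photosynthesis genes 17 of 31 fell and none rose, with a median of -0.37 (adjusted p = 1.31e-05). The 5' minus 3' index fell by 0.30 between the same groups, and with it as a covariate, an analysis added after the data were seen, the shorter photosynthesis list was not called (adjusted p = 0.0954), its mean going from -0.27 ± 0.03 to -0.21 ± 0.03 (SE). The wider list was still called, with means of -0.39 and -0.35.

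In all, 7274 of 22746 probe sets were called for SA in wild type, 3446 higher and 3828 lower. With a minimum of 2-fold the balance turned, with 1104 higher and 919 lower.

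**Figure D2:**
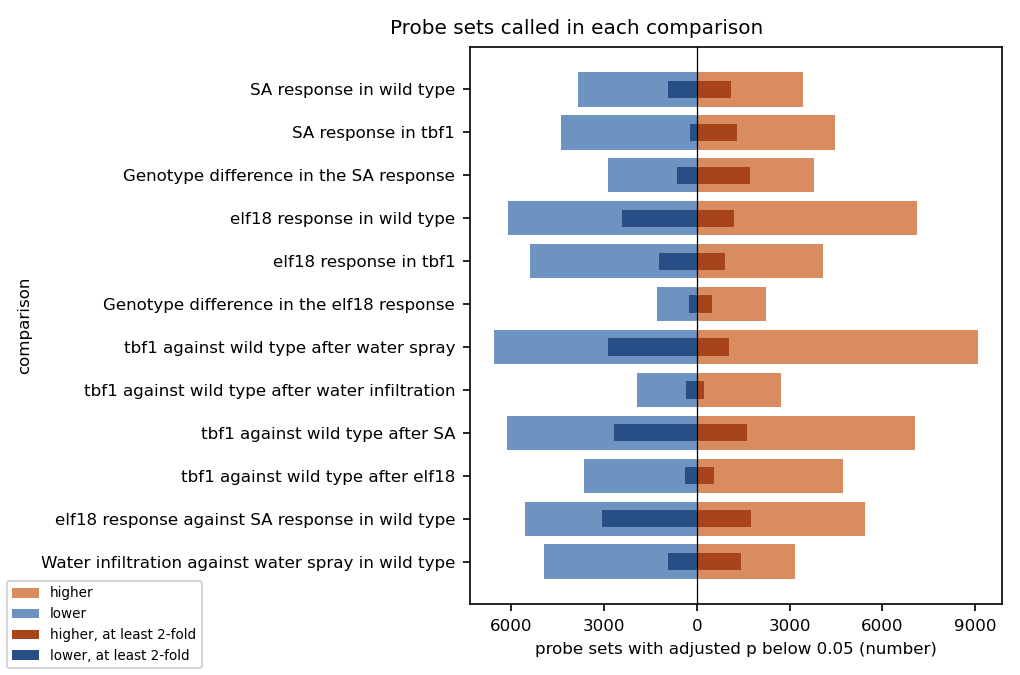
Number of probe sets called in each comparison (limma, adjusted p below 0.05, horizontal axis), higher to the right and lower to the left; dark bars give those with at least a 2-fold change. The longest bars belong to tbf1 against wild type after water spray, with 9085 higher and 6562 lower.

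In tbf1 SA raised AT3G02480 by 4.29 ± 0.23 (log2, SE, adjusted p = 4.08e-13), GRX480 by 3.69 ± 0.10, the calmodulin-like gene AT3G01830 by 3.39 ± 0.15 and UGT76B1 by 3.27 ± 0.35. AT5G46230, AT4G32870, AT3G47480, another calmodulin-like gene, and AT3G07590 rose by 2.75 to 3.26. AT3G28310 fell most, by 4.12 ± 0.15, followed by AT5G50335 at -2.51 and AT1G70270 at -2.44. Of the 8 ER folding and secretion genes 5 rose and none fell, with the same counts when adjusted over the list alone and a median of 0.78 (adjusted p = 0.00169, and adjusted p = 0.0645 with an estimated correlation). BZIP60, a transcription factor of the unfolded protein response, rose by 1.15 ± 0.09, ATERDJ3B by 0.89 ± 0.21 and AT2G34250 by 0.84 ± 0.12, while CRT1b was at 0.40 and BZIP28 at 0.16. The wider ER list had 27 of 34 genes higher and a median of 0.84 (adjusted p = 1.63e-14). After quantile normalization the median was 0.47 for ER folding and secretion and 0.52 for the wider ER list.

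Cytosolic ribosomal protein genes rose with SA in tbf1, 88 of 117 with 2 lower and a median of 0.61 (adjusted p = 6.10e-28). In wild type 23 rose and 25 fell, which was not called (adjusted p = 0.981). Of 9 ATG8 genes, which act in autophagosome formation, 8 rose in tbf1 and none fell, with a median of 0.74 (adjusted p = 8.25e-06); APG8A rose by 2.01 and ATG8B by 1.39. Of 7 pattern-triggered immunity genes 3 rose and none fell, with the same counts when adjusted over the list alone; the median of 0.26 turned to -0.03 under quantile normalization, where the call was lost with an adjusted p of 0.951 (adjusted p = 0.0196 as deposited, and adjusted p = 0.0645 with an estimated correlation). Of 9 photosynthesis and chlorophyll genes 3 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.971).

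The SA response in tbf1 took in 8849 probe sets, 4454 higher and 4395 lower. This balance was not kept: with a minimum of 2-fold 1313 were higher and 235 lower, and with median-centred arrays 4743 and 3684. With only the 6 arrays of its own groups fitted the count was 5209, 3160 higher and 2049 lower, and after quantile normalization it was 5851. The index differed by 0.14 between the groups, the hybridisation spike-ins by -1.03 and the 25S rRNA control probe set by -0.87.

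The 2 genotypes were then compared in their SA response, as the change in tbf1 minus that in wild type. AT3G28310 (-3.20 ± 0.21, log2 and SE), UGT76B1 (-2.97 ± 0.50, adjusted p = 4.89e-05), AT3G28510 (-2.67 ± 0.22), the EDS1-like gene AT3G48080 (-2.62 ± 0.25) and AT4G13180 (-2.43 ± 0.19) had the most negative differences. The most positive ones were those of AT3G02480 (4.32 ± 0.33), AT2G43550 (3.21 ± 0.16), AT5G48490 (3.18 ± 0.15), SWEET2 (3.18 ± 0.16), a sugar transporter of the vacuole, and AT5G52960 (2.92 ± 0.16). AT2G43550 and AT5G48490 were among the genes that fell most in wild type. GRX480, with a difference of -0.18, was not called. AT3G28310 was higher in tbf1 after water spray, by more than the size of its difference here. Its level in tbf1 was thus not below wild type after SA.

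Of the 8 ER folding and secretion genes 6 rose less in tbf1 and none rose more, with 7 lower when adjusted over the list alone and a median difference of -0.88 (adjusted p = 0.000471). This call was lost with an estimated correlation (adjusted p = 0.0852 with an estimated correlation). The differences were -1.54 ± 0.30 for ATERDJ3B, -1.38 ± 0.27 for CRT1b, -1.10 ± 0.25 for AT5G07340 and -0.93 ± 0.18 for AT1G29310, while AT2G34250 at -0.44 and BZIP60 at -0.15 were not called. The wider ER list was split, with 10 genes higher, 11 lower and a median of -0.19 (adjusted p = 0.586); after quantile normalization it was called as lower (adjusted p = 0.0034). AT4G29520 (-2.15) and PDIL5-1 (2.2), a protein disulfide isomerase-like gene, lay at its ends.

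**Figure D3:**
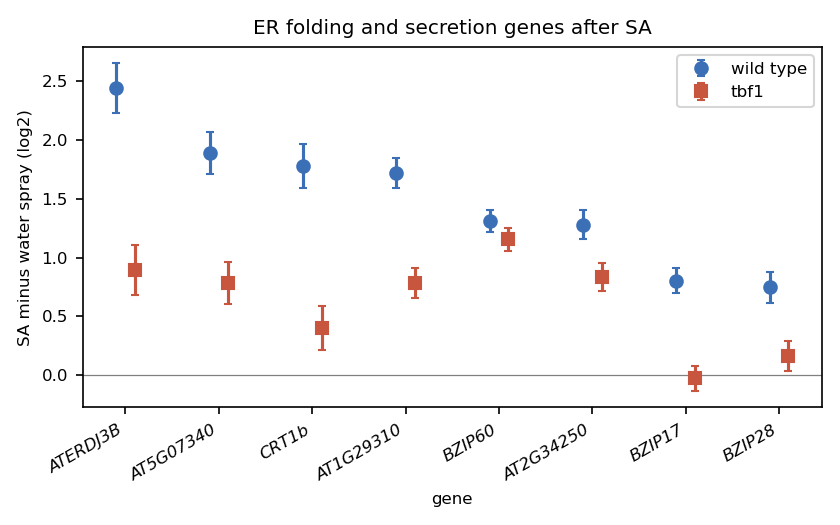
Change after SA (log2, vertical axis) of all 8 measured ER folding and secretion genes in wild type and tbf1; symbols give the estimate and bars the SE from limma, 3 arrays against 3. ATERDJ3B rose by 2.44 in wild type and by 0.89 in tbf1.

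Ribosomal protein genes had higher SA responses in tbf1, 68 of 117 with 2 lower and a median difference of 0.60 (adjusted p = 2.08e-20). ATG8 genes did so as well, 8 of 9 with a median difference of 0.89 (adjusted p = 5.19e-07). ATG8C had a difference of 1.87 and APG8A one of 1.60. The ribosomal protein genes were already lower in tbf1 after water spray (median -0.40, camera adjusted p = 1.24e-08). After SA their median difference between genotypes was 0.35, which was not called (camera adjusted p = 0.134). With the index as a covariate it was (camera adjusted p = 0.000341). Of 31 nuclear photosynthesis genes 14 had a more positive and 3 a more negative response, with a median difference of 0.32 (adjusted p = 0.00196, and adjusted p = 0.0853 with an estimated correlation). Of 7 pattern-triggered immunity genes 3 rose less in tbf1, and 4 when adjusted over the list alone (adjusted p = 0.0407, and adjusted p = 0.0903 with an estimated correlation). The call was also lost without any 1 of 4 of the 12 arrays, with adjusted p up to 0.0731. The genes included PUB24 at -1.24, WRKY53 at -0.85 and EFR at -0.67.

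The interaction was called in 6669 probe sets, 3780 positive and 2889 negative, or 1705 and 626 with a minimum of 2-fold. Of the 1104 probe sets that rose at least 2-fold in wild type, 64.7% rose less in tbf1, and of the 919 that fell at least 2-fold, 80.7% fell less; these were selected on the same wild type arrays, which favours smaller changes in tbf1. The index difference between the responses was 0.43. Between genotypes the index differed by -2.44 after water spray and by -2.01 after SA, so the tbf1 spray groups lay far below wild type. The value of 0.43 is the difference between these gaps and does not show that RNA quality was alike. Whether the lower index in the tbf1 spray groups made their SA response smaller in either direction was not tested.

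In wild type plants elf18 raised AT2G28710, a zinc finger gene, by 4.3 ± 0.09 (log2, SE, 3 arrays against 3, 19.7-fold, adjusted p = 2.31e-20). The rises of AT5G62150, AT3G18250, AT1G64405, PDF1.4, a defensin-like gene, AT1G28390, AT2G44380 and AT1G78410 lay between 3.20 and 3.45. BGLU44 (AT3G18080), a beta-glucosidase, fell most, at -4.02 ± 0.13. The peroxidase gene PRXR1 (AT4G21960) was at -3.88 ± 0.13, the GDSL lipase gene AT1G29660 at -3.75 ± 0.28 and AT1G73600, a phosphoethanolamine methyltransferase, at -3.64 ± 0.15. EXLA1 (AT3G45970), an expansin-like gene, was at -3.52 ± 0.12, CHI (AT2G43570), a chitinase family member, at -3.28 ± 0.22, AT3G26450 at -3.35 and AT4G16190 at -3.16.

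After elf18, 8 of 9 photosynthesis and chlorophyll genes fell in wild type, also when adjusted over the list alone, with a median of -1.50 (adjusted p = 1.10e-08). PORB was at -2.21 ± 0.12, PRK at -2.14 ± 0.10, the photosystem II gene PSBY at -2.06 and LHCB4.2, an antenna protein gene, at -1.60, while PSBW was at 0.11. In the wider nuclear list 29 of 31 fell, with a median of -1.31 (adjusted p = 4.51e-20). All 7 tubulin genes fell, with a median of -1.29 (adjusted p = 1.93e-06); TUB5 was at -2.84 and TUB6 at -2.12. Of 9 ATG8 genes 8 rose and 1 fell, with a median of 1.22 (adjusted p = 0.00145, and adjusted p = 0.177 with an estimated correlation). The 5' minus 3' index fell by 1.29 between the same groups, so each of these groups moved together with it.

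The pattern-triggered immunity list was not called for elf18 in wild type, with 3 genes higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.984). PUB22 was higher by 0.76, WRKY22 by 0.59 and PUB24 by 0.42, BIK1 was at -0.56, and EFR was at -0.23. Only 7 of the 33 genes fixed for this list had a named probe set. All 7 were already higher in wild type after water infiltration than after water spray, with a median of 3.46. Whether this left room for a further rise with elf18 was not tested. The ER folding and secretion list had 1 gene higher and 5 lower, also when adjusted over the list alone (adjusted p = 0.137); AT5G07340 was at -0.94 and BZIP28 at -0.91, and BZIP60 rose by 0.85. After quantile normalization that list was called as lower (adjusted p = 0.0493), while with the index as a covariate its mean turned from -0.35 ± 0.09 to 0.42 ± 0.20. In all 13221 probe sets were called, 7105 higher and 6116 lower, and the median over all probe sets was 0.13. The balance turned to 5757 higher and 6565 lower with median-centred arrays and to 5909 and 6094 after quantile normalization, and with a minimum of 2-fold it was 1196 and 2418. With the index as a covariate, 3774 were called, and the ATG8 list was not (adjusted p = 0.0628), its mean going from 1.06 ± 0.07 to 0.63 ± 0.17.

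In tbf1 elf18 raised the defensin genes PDF1.2 (AT5G44420) by 4.55 ± 0.13 (log2, SE, adjusted p = 6.89e-18) and PDF1.2b (AT2G26020) by 4.19 ± 0.09. These are close relatives, and their probe sets may share signal. AT3G18250, PDF1.4, AT2G28710, AT1G78410, AT2G44380 and AT1G65500 rose by 2.93 to 3.75. The plastid gene psaA was at -3.49 ± 0.38, AT2G34930 at -2.75 and AT1G04680 at -2.40. Of 9 photosynthesis and chlorophyll genes 7 fell, also when adjusted over the list alone, with a median of -0.95 (adjusted p = 2.15e-08); PRK was at -1.63 and PSBY at -1.61. Of 117 ribosomal protein genes 70 rose and 19 fell, with a median of 0.50 (adjusted p = 2.75e-10). All 7 tubulin genes fell (median -1.09, adjusted p = 9.59e-07), and 8 of 9 ATG8 genes rose (median 1.16, adjusted p = 1.72e-05).

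The elf18 response in tbf1 took in 9491 probe sets, 4083 higher and 5408 lower. The index fell by 1.19 here too, and with it as a covariate 2317 were called. The pattern-triggered immunity list (2 higher and 1 lower, adjusted p = 0.862) and the ER folding and secretion list (2 higher and 2 lower, adjusted p = 0.862) were not called; adjusted over the list alone, the counts were 2 and 1 for the former and 3 and 2 for the latter. With the index as a covariate the ER list was called as higher (adjusted p = 0.00558), its mean going from 0.11 ± 0.09 to 0.81 ± 0.18, and so was the wider ER list (adjusted p = 7.28e-05).

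Responses to elf18 in the 2 genotypes correlated at 0.83 across probe sets, which are not independent replicates, and those to SA at 0.41. The index changed alike in both elf18 responses, by -1.29 in wild type and -1.19 in tbf1. In the SA responses it changed by -0.30 in wild type and by 0.14 in tbf1, where the ranges of the 2 groups overlapped. Of the 6116 probe sets that fell after elf18 in wild type, 4331 also fell in tbf1, against 1454 for independent lists. Of the 7105 that rose, 3108 also rose, against 1275. After SA, 1856 of 3446 rose in both, against 674.8, and 1201 of 3828 fell in both, against 739.6. In opposite directions after SA, 917 that fell in wild type rose in tbf1 and 186 that rose fell; after elf18 these counts were 98 and 119.

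In the genotype difference of the elf18 response, AT1G29660 (2.60 ± 0.40, log2 and SE), AT1G73600 (2.51 ± 0.21), PDF1.2 (2.44 ± 0.19), BGLU44 (2.37 ± 0.18) and EXLA1 (2.19 ± 0.17) were the most positive. PDF1.2 rose more in tbf1 and the other 4 fell less. In tbf1 PDF1.2 was already lower after water infiltration, by more than its difference here, so it did not pass its wild type level after elf18. The most negative were psaA (-2.47 ± 0.54, adjusted p = 0.00242), AT5G10830 (-2.20 ± 0.22), AT5G17910 (-2.10 ± 0.25), AT1G62510 (-2.04 ± 0.25) and AT3G25130 (-1.88 ± 0.18). Of these, psaA was higher in tbf1 after water infiltration, by more than the size of its difference here. Its level in tbf1 was thus not below wild type after elf18. Of 9 photosynthesis and chlorophyll genes 6 fell less in tbf1, also when adjusted over the list alone, with a median difference of 0.51 (adjusted p = 3.41e-05). PORB differed by 0.80, LHCB4.2 by 0.70 and RCA, Rubisco activase, by 0.58. The nuclear photosynthesis list gave 15 of 31 higher and none lower (median 0.45, adjusted p = 9.95e-10), and ribosomal protein genes 50 of 117 higher and 2 lower (median 0.38, adjusted p = 1.94e-18). After quantile normalization neither photosynthesis list was called (adjusted p = 0.445 for the shorter and 0.472 for the wider list). The median of the ribosomal protein genes was then 0.20.

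Of the 8 ER folding and secretion genes 4 differed upward, also when adjusted over the list alone, with a median of 0.40 (adjusted p = 0.0103, and adjusted p = 0.157 with an estimated correlation). CRT1b differed by 1.07 and ATERDJ3B by 1.00. No pattern-triggered immunity gene was called, and none when adjusted over the list alone (camera adjusted p = 0.706); after quantile normalization the list was called as higher, the opposite direction (adjusted p = 0.0229). PUB22 was at -0.46 and WRKY22 at -0.15. The elf18 interaction took in 3524 probe sets, 2234 positive and 1290 negative. The index difference was 0.11.

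Without treatment by SA or elf18, the genes with the largest differences between genotypes were mostly others after spraying than after infiltration. After water spray AT3G28310 was higher in tbf1 by 3.58 ± 0.15 (log2, SE, adjusted p = 6.61e-15), QQS (AT3G30720), an Arabidopsis-specific gene linked to starch content, by 3.09 ± 0.12, and the iron-deficiency peptide gene AT1G47400 by 2.79 ± 0.12. GH9C2 was at -3.37 ± 0.23, AT4G16490 was at -3.21, psaA at -3.11 and AT3G51730 at -3.06. Photosynthesis and chlorophyll genes were lower in tbf1, 8 of 9 with none higher, also when adjusted over the list alone, with a median of -1.02 (adjusted p = 1.41e-06). PORB was at -1.95, PRK at -1.60 and LHCB4.1 at -1.55. All 7 tubulin genes were lower, with a median of -1.60 (adjusted p = 2.11e-07), as were 70 of 117 ribosomal protein genes with 25 higher (median -0.40, adjusted p = 1.24e-08).

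Of the 8 ER folding and secretion genes 5 were lower and 1 higher in tbf1 after water spray, or 5 and 2 when adjusted over the list alone, with a median of -0.85 (adjusted p = 0.0231, and adjusted p = 0.213 with an estimated correlation). ATERDJ3B was at -1.61 and CRT1b at -1.60. The call was lost after quantile normalization (adjusted p = 0.135), and with the index as a covariate the mean of the list changed sign, from -0.66 ± 0.09 to 0.80 ± 0.36 (adjusted p = 0.0658). Here 15647 probe sets were called, 9085 higher and 6562 lower, and the index differed by -2.44 between the same groups. The median change over all probe sets was 0.18, and median centring of the arrays lowered the share of higher calls from 58.1% to 48.0%. With a minimum of 2-fold most were lower, 2883 against 1037 higher. With the index as a covariate 217 were called, and further list calls were lost. The mean went from -1.02 ± 0.03 to -0.52 ± 0.14 for photosynthesis and chlorophyll (adjusted p = 0.0658), from -1.66 ± 0.07 to -0.96 ± 0.31 for tubulins (adjusted p = 0.0668) and from -0.43 ± 0.02 to -0.17 ± 0.11 for ribosomal proteins (adjusted p = 0.405).

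After water infiltration 4679 probe sets differed, 2734 higher and 1945 lower, but 240 and 358 with a minimum of 2-fold. Higher in tbf1 were psaA by 3.11 ± 0.38 (log2, SE, adjusted p = 1.27e-06), COR27, a cold-regulated gene, by 1.97 ± 0.18, and ARA12, a subtilisin-like protease gene, by 1.79 ± 0.15. PDF1.2 was at -2.96 ± 0.13, AT1G76960 at -2.65, PDF1.2b at -2.47 and CHI at -2.34. Of 7 pattern-triggered immunity genes 4 were lower and 1 higher in tbf1, or 4 and 2 when adjusted over the list alone, with a median of -0.41 (adjusted p = 0.0477, and adjusted p = 0.201 with an estimated correlation). WRKY22 was at -1.16 and EFR at 0.69. Of 8 ER folding and secretion genes 4 were lower and 1 higher, or 5 and 2 when adjusted over the list alone (median -0.51, adjusted p = 0.0477, and adjusted p = 0.229 with an estimated correlation); BZIP60 was at -1.0, CRT1b at -0.98 and AT2G34250 at 0.64. Both calls were lost without any 1 of 3 of the 6 arrays, with adjusted p up to 0.0837. No photosynthesis and chlorophyll gene was called in limma, and none when adjusted over the list alone (camera adjusted p = 0.140), with PORB at 0.33 and PSBY at 0.27. The index was higher in tbf1 by 0.54, and with it as a covariate 2715 probe sets were called. The pattern-triggered immunity list was then not called (adjusted p = 0.0612), with a mean of -0.27 in both fits. The mean of the ER folding and secretion list went from -0.39 ± 0.09 to -0.71 ± 0.10. The wider ER list was called with the covariate (camera adjusted p = 0.0165), its mean going from -0.11 ± 0.06 to -0.29 ± 0.07.

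After SA 13208 probe sets differed between the genotypes, 7067 higher and 6141 lower, with a median of 0.14 over all probe sets; the balance turned to 5586 higher and 6562 lower with median-centred arrays and to 5807 and 6239 after quantile normalization, and it was 1607 and 2682 with a minimum of 2-fold. Higher in tbf1 were AT3G02480 by 4.47 ± 0.23 (log2, SE, adjusted p = 6.13e-14), STOMAGEN by 3.77 ± 0.15 and DI21, a drought-induced gene, by 3.40 ± 0.12. AT5G17760 was at -3.69 ± 0.17, the ubiquitin ligase gene RING1 (AT5G10380) at -3.54 ± 0.16, ATERDJ3B at -3.15 ± 0.21 and CRT1b at -2.97 ± 0.19. Of the 8 ER folding and secretion genes 7 were lower and 1 higher, also when adjusted over the list alone, with a median of -1.37 (adjusted p = 1.82e-05); BZIP60 was the 1 higher gene, at 0.29. Of 9 photosynthesis and chlorophyll genes 7 were lower and 1 higher, also when adjusted over the list alone (median -0.70, adjusted p = 0.000188). The pattern-triggered immunity list, with 1 higher and 3 lower by both adjustments, the second adjusted over the list alone, was not called (adjusted p = 0.177). The index differed by -2.01, and with it as a covariate 1367 probe sets were called and neither the ER nor the photosynthesis list was (adjusted p = 0.470 for both). Their means went from -1.53 ± 0.09 to -0.33 ± 0.30 and from -0.76 ± 0.03 to -0.35 ± 0.11.

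After elf18 8383 probe sets differed, 4721 higher and 3662 lower. ARA12 was higher in tbf1 by 1.76 ± 0.15 (log2, SE, adjusted p = 3.10e-09), AT1G12800 by 1.69 and BGLU44 by 1.69. AT1G76960 was at -2.63 ± 0.11, AT5G05300 at -2.27 ± 0.11 and AT2G18220 at -2.26 ± 0.14. Photosynthesis and chlorophyll genes were higher in tbf1, 8 of 9 also when adjusted over the list alone, with a median of 0.64 (adjusted p = 5.58e-06); this call was lost after quantile normalization (adjusted p = 0.430). Of 7 pattern-triggered immunity genes 5 were lower and 2 higher, also when adjusted over the list alone (adjusted p = 0.0842), with WRKY22 at -1.31 and EFR at 0.64. The ER folding and secretion list had 1 higher and 1 lower, also when adjusted over the list alone (adjusted p = 0.520). The index was higher in tbf1 by 0.64, and with it as a covariate 4197 probe sets were called.

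The responses of wild type plants to elf18 and SA differed most in UGT76B1, at -6.88 ± 0.50 for elf18 minus SA (log2, SE, adjusted p = 3.68e-11), AT5G55450 at -5.23, CHI at -5.06 and the lectin-like gene AT5G03350 at -4.95. AT5G48490 at 4.83 ± 0.15, AT2G28710 at 4.70 ± 0.13, AT4G21870 and AT5G01015 at 4.19 each and STOMAGEN at 3.99 were most positive. All 8 ER folding and secretion genes were lower for elf18, also when adjusted over the list alone, with a median of -1.81 (adjusted p = 3.77e-07). Of 9 photosynthesis and chlorophyll genes 7 were lower and 1 higher, also when adjusted over the list alone (median -1.37, adjusted p = 1.80e-06). Of 7 pattern-triggered immunity genes 4 were lower and 2 higher, also when adjusted over the list alone (adjusted p = 0.00922), with WRKY53 and PUB24 among the lower. All 7 were already higher in wild type after water infiltration than after water spray, with a median of 3.46.

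Both treatments lowered 1840 probe sets, against 1029 for independent lists, and raised 849, against 1076. In opposite directions, 1436 rose with SA and fell with elf18, and 1004 fell with SA and rose with elf18. The correlation across probe sets was 0.05. The difference was called in 11001 probe sets, 5442 higher and 5559 lower, or 1746 and 3052 with a minimum of 2-fold, and in 5844 with the index as a covariate; the index differed by -1.0, and the treatments differed also in route and time.

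Water infiltration for 2 h and water spray for 6 h were compared in wild type as the background of both treatments. All 7 pattern-triggered immunity genes were higher after infiltration, also when adjusted over the list alone, with a median of 3.46 (adjusted p = 7.24e-16). PUB22 (AT3G52450), a U-box ubiquitin ligase, was higher by 5.48 ± 0.15 (log2, SE, 44.6-fold), and AT2G43620, a chitinase family member, and AT4G22470 by 6.75 each. XTH18, a cell wall enzyme, was higher by 5.55 and the calmodulin-like gene AT3G01830 by 5.86. AT5G48490 was at -4.11, STOMAGEN at -3.44 and EXPA8, an expansin, at -2.86.

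Of the 117 ribosomal protein genes 96 were lower after infiltration and 2 higher, with a median of -0.54 (adjusted p = 2.55e-18). Of the photosynthesis and chlorophyll genes 6 of 9 were lower, also when adjusted over the list alone (median -0.46, adjusted p = 0.000723). Of 8 ER folding and secretion genes 4 were higher, or 5 when adjusted over the list alone (median 0.38, adjusted p = 0.00413, and adjusted p = 0.0862 with an estimated correlation). In all 8138 probe sets were called, 3181 higher and 4957 lower, but 1434 and 937 with a minimum of 2-fold. The index differed by -0.47, and route and time cannot be separated here.

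**Figure D4:**
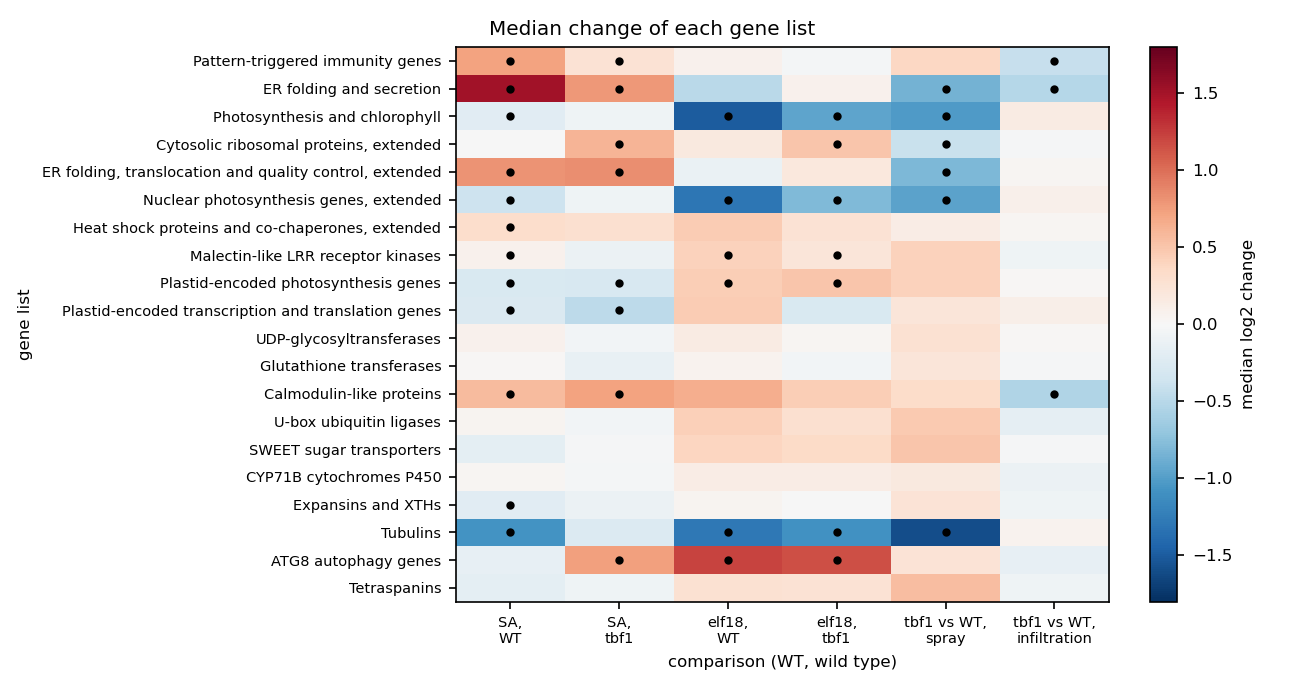
Median log2 change (colour) of each gene list (vertical axis) in 6 comparisons (horizontal axis); black dots mark camera adjusted p below 0.05 at the preset correlation. The ER folding and secretion list is at 1.51 after SA in wild type and 0.78 in tbf1.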

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

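The correlation with the trend inside groups, the covariate fits and the splits with the main effect taken out were chosen after the results they bear on, or the data, were seen. Results appear here because a test of the difference between genotypes passed, or because control probe sets outside the comparisons changed between groups. Groups of 3 arrays were not searched for single arrays far from the others.

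The SA response differed between genotypes in 6669 probe sets. Among genes, AT3G02480 (4.32), AT2G43550 (3.21), AT5G48490 (3.18), SWEET2 (3.18) and AT5G52960 (2.92) had the most positive differences (log2, tbf1 minus wild type). AT3G28310 (-3.20), UGT76B1 (-2.97), AT3G28510 (-2.67), AT3G48080 (-2.62) and AT4G13180 (-2.43) had the most negative. List medians differed by -0.39 for pattern-triggered immunity, -0.88 for ER folding and secretion, 0.60 for ribosomal proteins, 0.32 for nuclear photosynthesis genes, 0.19 for SWEET sugar transporters and 0.89 for ATG8 genes. The calls of pattern-triggered immunity (adjusted p = 0.0903 with an estimated correlation), ER folding and secretion (0.0852), nuclear photosynthesis genes (0.0853) and SWEET transporters (0.239) were lost with that setting, the last also without any 1 of 2 of the 12 arrays. Of the 16 genes named for SA in wild type 15 differed between genotypes, against 29.3% of all probe sets. They were picked on the same wild type arrays, which favours smaller changes in tbf1. When genotype labels were exchanged within treatments, 16 of 100 splits, the real one included, gave as many probe sets, with up to 11586 in another split, so chance could not be excluded by that test. Such splits carry the main effect of genotype, which is the difference averaged over the SA and water arrays. With this main effect taken out, a test chosen after the first was seen, only the real split (1 of 100) reached 6669. The highest other gave 2608.

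The elf18 response differed in 3524 probe sets. AT1G29660 (2.60), AT1G73600 (2.51), PDF1.2 (2.44), BGLU44 (2.37) and EXLA1 (2.19) had the most positive differences, and psaA (-2.47), AT5G10830 (-2.20), AT5G17910 (-2.10), AT1G62510 (-2.04) and AT3G25130 (-1.88) the most negative. List medians differed by 0.40 for ER folding and secretion, 0.51 for photosynthesis and chlorophyll, 0.38 for ribosomal proteins, 0.18 for the wider ER list, 0.45 for nuclear photosynthesis genes, -0.42 for plastid-encoded transcription and translation genes and 0.36 for tubulins. The calls of ER folding and secretion (adjusted p = 0.157 with an estimated correlation), the wider ER list (0.207), the plastid list (also 0.207) and tubulins (0.202) were lost with that setting. After quantile normalization those of photosynthesis and chlorophyll (0.445), nuclear photosynthesis genes (0.472) and tubulins (0.154) were lost. Of the 16 genes named for elf18 in wild type 12 differed, against 15.5% of all probe sets. These too were picked on the same wild type arrays. As many probe sets were called in 3 of 100 splits, with up to 8685 in another, and in 1 of 100 with the main effect taken out, where the highest other gave 294.

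For elf18 against SA in wild type, 3 of 100 splits gave at least 11001 probe sets, with up to 13112 in another, and 1 of 100 did with the main effect taken out, where the highest other gave 5788. For comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real split was the 1 that gave the most, with 7274 for SA in wild type, 13221 and 9491 for elf18 in wild type and tbf1, 15647 and 4679 for the genotypes after water spray and water infiltration, 8383 after elf18 and 8138 for infiltration against spray, where the highest other gave 0. It gave 8849 for SA in tbf1, with 155 in the highest other, and 13208 for the genotypes after SA, with 1.

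The 5' minus 3' index of control probe sets changed by -0.30 with SA in wild type, by -1.29 and -1.19 with elf18 in wild type and tbf1, and by -0.47 from water spray to water infiltration. Between genotypes it differed by -2.44 after water spray, 0.54 after water infiltration, -2.01 after SA and 0.64 after elf18. Hybridisation spike-ins, which are added to the samples in fixed amounts, changed by -1.03 with SA in tbf1, 1.70 with elf18 in wild type, 1.89 between genotypes after water spray and -1.36 after elf18. The 25S rRNA control probe set changed by -0.87 with SA in tbf1 and differed by 1.49 between genotypes after water spray.

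The first pattern weighed was the number of probe sets that differed between genotypes after water spray, 15647 against 4679 after water infiltration. Across probe sets, which are not independent replicates, the trend on the index inside groups correlated with the change at -0.35. Of 100 assignments of the index, the real one included, 2 gave as large a value, which goes with a contribution of RNA integrity. Other comparisons gave similar shares, but their index differed too, and the correlation had its sign. It was -0.30 for the genotypes after SA (index -2.01, 3 of 100) and -0.23 for elf18 in tbf1 (-1.19, 2 of 100). For the genotypes after water infiltration it was 0.05 (0.54, 2 of 100). The sign was opposite for SA in wild type, at 0.13 (-0.30, 31 of 100), and infiltration against spray, at 0.04 (-0.47, 39 of 100). Probe sets of the same gene also disagreed more, relative to their shared change, than after water infiltration (ratio 1.50, 95% bootstrap interval 1.01 to 2.2, 152 genes). This relative disagreement, 0.65 after water spray, followed the index only in part. It was 0.61 for the genotypes after SA and 0.64 for elf18 in wild type (index -2.01 and -1.29). For SA in wild type it was 0.33 and for infiltration against spray 0.32 (-0.30 and -0.47). Yet it was 0.62 for the genotypes after elf18 (0.64) and 0.85 in the elf18 interaction (0.11), where paired probe sets correlated at 0.02. Not scaled by the shared change, the median difference between paired probe sets was 0.56 after water spray. It was 0.53 for the genotypes after SA, 0.47 for elf18 in wild type and 0.37 in the elf18 interaction. For the genotypes after elf18 it was 0.32, for SA in wild type 0.24 and for the genotypes after water infiltration 0.23. With the index as a covariate 217 were called: the median SE grew from 0.14 to 0.72 and the estimates moved as well, with a median size of 0.66 before and 0.76 after among the probe sets called before and the same sign in 66.3% of them. A contribution of RNA integrity and a difference between genotypes in water-sprayed plants both stay open, since the index follows whole groups. The 2 were not tested apart.

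The second was the fall of nuclear photosynthesis genes after elf18 in wild type. Its mean of -1.21 ± 0.03 (SE) was -1.03 ± 0.08 with the index as a covariate, which argues against the trend inside groups as its whole cause. A steeper effect of RNA integrity beyond the range found inside groups, and a response to elf18, stay open.

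The third was the smaller rise of the 8 ER folding and secretion genes with SA in tbf1. This list call was lost with an estimated correlation (camera adjusted p = 0.0852). The wider ER list of 34 genes was not called (camera adjusted p = 0.586). Its mean difference was -0.10 ± 0.08, and -0.24 ± 0.08 with the covariate. For the 8 genes the mean difference of -0.87 ± 0.13 was -1.13 ± 0.11 with the covariate. This argues against the same trend as the cause of the difference in these 8 genes. The same covariate turned the mean of the 8-gene list from -0.35 ± 0.09 to 0.42 ± 0.20 for elf18 in wild type. That list therefore does move with the index. A dependence on the genotype stays open as a hypothesis, as does an effect of RNA integrity that is not linear.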

How the results depend on the processing

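The index as a covariate, the robust eBayes fit and the averaging of probe sets per gene were chosen after seeing the data. The 17 further lists were also added after the data had been opened, from gene names alone and before the values of any gene had been tested. The planned filter on dim probe sets and the intensity trend were not run, because centred values hold no brightness, which also leaves signal over background unknown.

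With the replicate number as a block, every count of probe sets stayed within 1.5 times the reported one, from 3710 for the elf18 interaction to 15796 for the genotypes after water spray, and 24 list tests were called as before. The labels do not say that a number marks a shared batch, and of 84 pairs of arrays with equal numbers 18 correlated above 0.1 (range -0.16 to 0.28, median 0.05). Control levels did follow the number: from replicate 1 to 3 the hybridisation spike-ins were lower in 8 of 8 groups (mean difference -0.94) and the 25S rRNA probe set higher in 8 of 8 (0.49), so arrays with equal numbers may share a processing step. Median centring, the robust fit and 1 value per gene also kept every count within 1.5 times, although the majority direction turned with median centring for elf18 in wild type and for the genotypes after water spray and after SA. It also turned after quantile normalization for elf18 in wild type and the genotypes after SA, with the block for SA in tbf1, and with only the arrays compared for elf18 against SA. With the covariate it turned for elf18 in both genotypes and for the genotypes after both water treatments. With a minimum of 2-fold it turned for SA and elf18 in wild type, for the genotypes after water spray, water infiltration and SA, and for infiltration against spray, and at an adjusted p under 0.01 for elf18 in wild type and the genotypes after SA.

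With only the arrays of its own groups the SA response in tbf1 gave 5209 probe sets, and after quantile normalization 5851. Fitted on their own arrays, the genotypes after water spray, which share the group with the widest spread, also gave fewer (13037 against 15647). Counts were higher for SA in wild type (8791 against 7274) and for the genotypes after water infiltration (6932 against 4679). The cause was not tested. At an adjusted p under 0.01 the elf18 interaction gave 1971 and the genotypes after water infiltration 3089. With a minimum of 2-fold, which removes small changes by construction, the counts were 2023, 1548 and 2331 for SA in wild type, in tbf1 and their difference, and 3614, 2149 and 750 for elf18. They were 3920, 598, 4289 and 930 for the genotypes after water spray, water infiltration, SA and elf18, 4798 for elf18 against SA and 2371 for infiltration against spray.

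With the index as a covariate the counts were 3774 and 2317 for elf18 in wild type and tbf1, 217, 2715, 1367 and 4197 for the genotypes after water spray, water infiltration, SA and elf18, and 5844 for elf18 against SA. The median SE grew in each of them. The other 5 counts stayed within 1.5 times. Of the 192 named values 22 were no longer called, and AT4G15545 after water spray turned from -2.84 to 0.52 (adjusted p = 0.744).

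Of 24 calls for the 3 lists fixed beforehand over 12 contrasts, 14 held with an estimated correlation; for pattern-triggered immunity 3 of 6 held, and for ER folding and secretion 3 of 9. Counted by the direction that camera or fry gave, and only where either fit made a call, list directions reversed in 6 cases, whose cause was not tested. With the covariate these were ER folding and secretion (adjusted p = 0.0658) and the wider ER list (0.568) between genotypes after water spray, and the wider ER list after elf18 (0.80). After quantile normalization they were pattern-triggered immunity in the elf18 interaction (0.0229) and ribosomal proteins between genotypes after water infiltration (0.0186), and by fry expansins and XTHs for infiltration against spray (0.00102). Signs also turned outside these cases: over all 240 list tests, called or not, the mean did so in 21 with the covariate, and the median in 23 with median centring and 29 after quantile normalization.

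Without each array in turn the counts ranged from 6413 to 6567 for SA in wild type, 7751 to 9379 in tbf1 and 5849 to 7274 for their difference. For elf18 they ranged from 11271 to 12487, 7717 to 9019 and 2824 to 3584. For the genotypes they ranged from 13773 to 15254 after water spray, 3482 to 4006 after water infiltration, 11642 to 12327 after SA and 6729 to 7854 after elf18. They ranged from 9770 to 10933 for elf18 against SA and 7236 to 7570 for infiltration against spray, and list calls from 21 to 25.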

Other observations

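The gene groups and arrays described here were reported as measured, and no further hypothesis was tested. Malectin-like receptor kinases, a family of plasma membrane proteins, had 23 of 33 genes higher and 2 lower after elf18 in wild type, with a median of 0.42 (log2, camera adjusted p = 0.0199); the list was not called after quantile normalization (adjusted p = 0.155) or with the 5' minus 3' index as a covariate (adjusted p = 0.0760), its mean going from 0.43 ± 0.02 to 0.38 ± 0.06. Heat shock proteins and co-chaperones had 7 of 18 genes higher and 2 lower after SA in wild type, with a median of 0.31 (adjusted p = 0.0024). Expansins and XTHs, which act on cell walls, had 1 of 27 higher and 10 lower after SA in wild type (median -0.21, adjusted p = 0.00505).

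Plastid-encoded photosynthesis genes had 25 of 43 higher and 8 lower after elf18 in wild type, with a median of 0.45 (adjusted p = 0.0358), while the nuclear list had a median of -1.31. The plastid call was lost with an estimated correlation (adjusted p = 0.683 with an estimated correlation) and without any 1 of 3 of the 6 arrays (adjusted p up to 0.0773), and the difference between the lists was not tested. The 5' minus 3' index fell by 1.29 between these groups.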
